A study of Homo sapiens with 24 samples.

How the data were processed

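Total RNA of Huh7 hepatoma cells, wild type (WT) or *ABHD6* knockout (KO), was extracted with a Qiagen RNeasy kit, made into libraries with an Illumina TruSeq directional mRNA kit and sequenced on an Illumina NovaSeq. The cells were harvested in basal medium (0 h) or after 24 h or 48 h in 800 µM palmitic acid, with 4 libraries in each of the 6 groups. The deposited table holds FPKM values (fragment counts scaled to transcript length and to the mapped fragments of the library) made by the authors, whose notes name GRCh38, STAR, Cufflinks and Cuffdiff without versions, roles or a strand setting. It has 58024 Ensembl gene IDs and 24 columns, 1 per library. No scaling between libraries is stated, and the main fit had none. Summed FPKM was 1031360 to 1213280 per library at 0 h and 748252 to 995833 later. The protocol gives a harvest on day 1 only, and times came from sample labels and the design summary.

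Fragment counts were not used here. The number of fragments behind each library was read from the smallest steps of the FPKM values on genes with a single transcript of at least 1500 bp, and lay between 398757 and 721321. Gene symbols, types and exon positions came from GENCODE release 29, which matched 57416 IDs (99.0%). The 45 copies of genes in the shared region of chromosome Y, all at 0, were left out.

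Values were compared as log2(FPKM + 0.5) for the 17252 genes with a mean of at least 0.5 FPKM over the 24 libraries; 40727 genes fell below that floor. A single fit of 6 group means in limma 3.58.1 (R 4.3.3), with an intensity trend in the variance, gave 18 residual degrees of freedom and a prior of 4.63. The 11 comparisons were KO against WT at each time, 24 h and 48 h against 0 h and 48 h against 24 h in each genotype, and the difference of the KO and WT responses at 24 h and 48 h (interaction). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in a comparison, and a further count took those with an absolute log2 fold change of at least 1. No fold is given against a group whose libraries are all listed at 0, other than for *ABHD6* under another pseudocount.

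The 30 gene lists were fixed before the data were examined. They covered monoacylglycerol and endocannabinoid genes, PPAR alpha targets, mitochondrial beta oxidation, fatty acid synthesis, cholesterol synthesis, triglyceride synthesis and lipid droplets, lipoprotein assembly, phospholipid and sphingolipid metabolism, ATF4 targets, ER chaperones and degradation, NF-kB genes, interferon response, acute phase, apoptosis, NRF2 genes, metallothioneins, lysosome and autophagy, hepatocyte identity, G2/M, G1/S, hypoxia and glycolysis, nuclear OXPHOS subunits, EMT and matrix, immediate early genes, stellate, immune, endothelial and biliary markers, and mitochondrially encoded and ribosomal protein genes as signs of RNA quality. Some genes are in more than 1 list. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison, and fry gave the direction within a list. The genes considered for naming, not all of which are printed, were selected by a rule: *ABHD6*; the 6 highest and 6 lowest folds per comparison, other than 48 h against 24 h, among called genes that changed at least 2-fold, had a mean of at least 5 FPKM in the higher group, a symbol that is not a clone or antisense name, and no overlap between the 4 and 4 libraries; and up to 4 called members of each list described.

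Alternatives fixed before the data were examined were pseudocounts of 0.1 and 1, no filter and a filter at 2 FPKM, median-of-ratios rescaling, quantile normalization, a fit of only the groups compared, no variance trend, robust variance, array weights, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were the tests without genes listed at 0 in a whole group while another group averaged at least 5 FPKM, the tests of only genes with no opposite-strand exon overlap, quantile normalization for the lists, and correlations over genes at 20 FPKM or more. Group labels were also permuted, over all 35 splits of 8 libraries, or 100 drawn splits for an interaction. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.

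The fit was tested on simulated data in which 200 of 17201 genes were changed between KO and WT at 0 h, with noise settings chosen after comparison with the real spread. It called 5 of 53 genes changed 2-fold at 5 to 20 FPKM, 27 of 47 at 20 FPKM or more, and 34 of 61 and 38 of 39 of those changed 4-fold. Of 175 genes called 59 had not been changed, or 23 of 139 at 5 FPKM or more, a share above the nominal 0.05. In a comparison with no changed gene 3 were called.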

Results

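Huh7 cells, a human hepatoma line, were profiled as wild type (WT) and as a knockout (KO) of *ABHD6*, which encodes a serine hydrolase that cleaves monoacylglycerols. RNA was taken in basal medium (0 h) and after 24 h and 48 h with 800 µM palmitic acid, a saturated fatty acid. Each of the 6 combinations had 4 libraries, 24 in all. No library had the same time in culture without palmitic acid, so the acid and the time in culture changed together. The labels do not say whether the 4 libraries of a group came from separate cultures or how many KO clones were used, so p-values measure the spread between these libraries and treat them as independent. The smallest values stepped in units of about 1 fragment, which placed the number of fragments behind the values at 398757 to 721321 per library, and 12894 to 15334 genes per library were above 0. At that depth 1 fragment on a 2 kb transcript equals 0.693 to 1.25 FPKM. Pearson correlations of replicates over genes with mean FPKM of at least 20 lay between 0.816 and 0.881, across genes that are not independent replicates. Changes are given below as log2 fold changes ± their standard error (SE), from 4 libraries per group.

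*ABHD6* itself (ENSG00000163686.14, chromosome 3, 58237506 to 58295693, GRCh38) was too low to check the genotype labels. It was above 0 in 7 of 24 libraries, 3 of 12 WT and 4 of 12 KO. Those 7 values lay between 0.693 and 1.16 FPKM, or 1.63 to 1.79 fragments over the full exon length. Its mean of 0.239 FPKM was below the floor of 0.5 for testing, and no gene is annotated on its opposite strand. Without that floor, its difference between KO and WT had an adjusted p of 0.945 at 0 h, 1 at 24 h and 0.86 at 48 h. A difference was not detectable in these values. The strand setting of the counting is not given, and with the opposite setting most reads of *ABHD6* would be left out of its value.

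Genes annotated as antisense held 44.0% to 58.1% of the summed FPKM of each library. Over 512 pairs of an antisense gene and the gene it overlaps, the antisense gene had the higher mean in 422 (82.4%), with a median log2 ratio of 4.08. *AC006064.4*, antisense to the glycolytic gene *GAPDH*, averaged 37290 FPKM against 239 for *GAPDH*. The setting for strand in the counting is not given in the sources used here, so the values of antisense genes and of genes whose exons overlap an opposite-strand gene are uncertain, and such genes are marked ° below. The others are not free of this doubt: with the opposite setting they would hold only stray reads of the other strand. A † marks a gene whose call against 0 h was lost in 4 or more of the 8 fits with 1 library left out. Folds of genes mostly at 0 at 0 h depend on the pseudocount: 3 of 4 libraries were at 0 for *AREG* and *HERPUD1* in WT and *AREG*, *ATF3* and *NDRG1* in KO. The antisense share was 57.0% ± 0.867 in WT and 57.2% ± 0.551 in KO at 0 h (SD, n = 4), 47.0% ± 1.55 and 47.1% ± 0.639 at 24 h, and 45.9% ± 1.37 and 44.6% ± 0.491 at 48 h. Mitochondrially encoded genes held 3.53% ± 0.291 and 3.89% ± 0.519 at 0 h, 12.3% ± 0.913 and 11.5% ± 0.961 at 24 h, and 11.1% ± 0.787 and 13.8% ± 0.798 at 48 h. All shares at 24 h and 48 h lack *MT-CO1*, and that of WT at 48 h also *MT-CO3*, *MT-ATP6* and *MT-ATP8*, listed at 0 there; over 8 genes never at 0 KO was lower than WT at 48 h (median log2 difference -0.46). Fragments behind the values were 442125 ± 31071 in WT and 438006 ± 44848 in KO at 0 h, and 642255 ± 54689 and 684821 ± 31690 at 48 h.

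**Figure D1:**
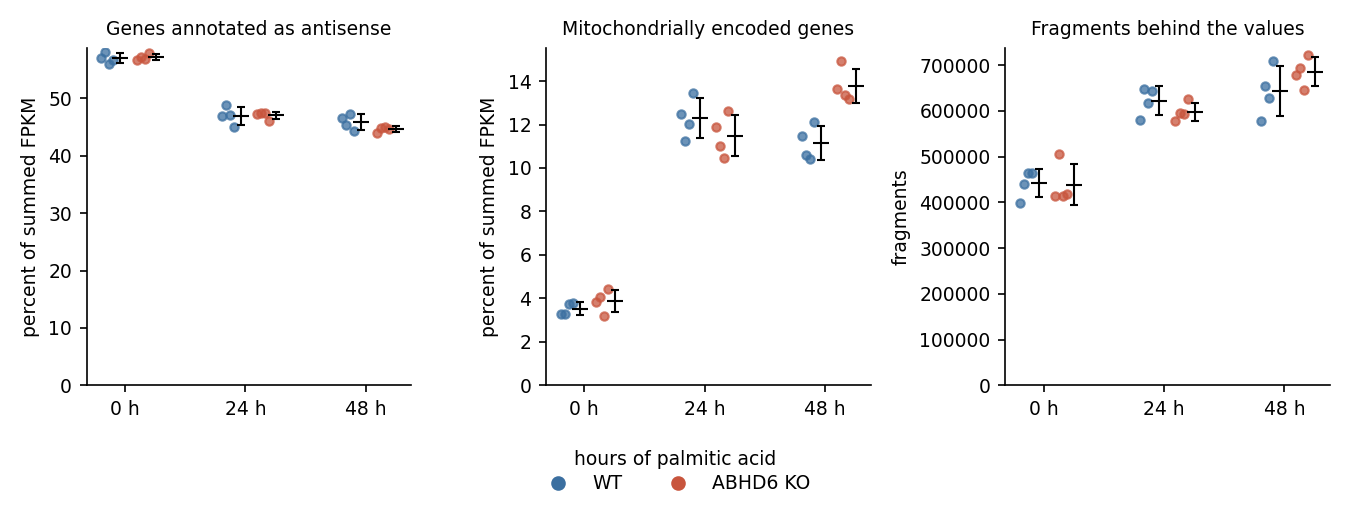
Share of summed FPKM in genes annotated as antisense (left, percent), share in mitochondrially encoded genes (middle, percent) and fragments behind the values (right) in each library, by hours of palmitic acid and genotype. Points are libraries, bars the mean ± SD of 4; all 8 libraries at 0 h lie above the other 16 in antisense share and below them in mitochondrial share and in fragments. Listed at 0 and so missing from the mitochondrial share are *MT-CO1* at 24 h and 48 h and 3 more genes in WT at 48 h.

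WT cells after 24 h of palmitic acid were compared with WT cells in basal medium to find the genes that change under the acid. Genes of the unfolded protein and integrated stress responses rose: *HERPUD1* (4.71 ± 0.84), a component of endoplasmic reticulum (ER) associated degradation, *HSPA5* (1.41 ± 0.19), the main ER chaperone, *ATF3* (3.42 ± 0.64), a stress transcription factor, and *PPP1R15A* (2.84 ± 0.30), which directs dephosphorylation of eIF2α. *HSPA5* went from 55.6 ± 9.77 to 152 ± 47.1 FPKM (SD, n = 4). The growth factor *AREG*, a ligand of the EGF receptor, rose by 4.79 ± 0.65 and *CXCL5*, a neutrophil chemokine, by 2.22 ± 0.28. *FADS1*° (-1.09 ± 0.17), the delta-5 desaturase, fell and *CYP51A1*° (0.74 ± 0.16) rose. limma called 701 of 17252 genes, 252 higher and 449 lower, and 415 of them changed at least 2-fold. With median-of-ratios rescaling the calls were 311 higher and 362 lower, and with quantile normalization 296 higher and 248 lower.

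Of 25 tested ATF4 targets, 5 rose. Within the list 10 rose adjusted over the list alone (camera adjusted p = 6.47e-06). Those over all genes included *SLC7A11*°† (1.16 ± 0.30) and *DDIT3*°† (1.09 ± 0.31), the cystine transporter and the factor CHOP. Of 26 ER chaperone and degradation genes 4 passed as higher, including *HYOU1*°† (1.03 ± 0.29) and *HSP90B1*°† (0.74 ± 0.18). Among the members 6 rose adjusted over the list alone (camera adjusted p = 0.00205; adjusted p = 0.0738 with an estimated correlation). NRF2 oxidative stress genes had 5 of 23 higher, with *SRXN1* (2.42 ± 0.52), *GCLC*° (1.99 ± 0.46) and *TXNRD1* (0.99 ± 0.20). For the list 5 rose adjusted over the list alone (camera adjusted p = 0.000241; adjusted p = 0.0706 with an estimated correlation). In the NF-kB list 1 of 16 rose. In that list 5 rose adjusted over the list alone (camera adjusted p = 0.000248). In the lysosome and autophagy list 1 of 30, *SQSTM1*° (0.72 ± 0.18), rose. Of the members 1 rose adjusted over the list alone (camera adjusted p = 0.00591). Hepatocyte identity genes fell as a list, with 2 of 25 passing, *FOXA1*° (-1.99 ± 0.44) and *FGB*† (-0.60 ± 0.16). Of its members 3 fell adjusted over the list alone (camera adjusted p = 0.00962; adjusted p = 0.109 with an estimated correlation). The G2/M list was lower with 0 of 24 members passing. Within the list 0 passed adjusted over the list alone (camera adjusted p = 0.0241). Of the mitochondrially encoded genes 12 of 13 rose and 1 fell, with the same 12 and 1 adjusted over the list alone (median 2.04, camera adjusted p = 3.79e-36); *MT-CO1*, at 348 to 464 FPKM at 0 h, was listed at 0 in all 4 libraries at 24 h.

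The highest folds by the fixed rule were *CYSRT1* (4.93 ± 0.68), *AREG* (4.79 ± 0.65), *HERPUD1* (4.71 ± 0.84), *RPS9P1*° (4.60 ± 0.86) and *LILRB3* (4.08 ± 0.65), with *CCDC200*°†, which was listed at 0 at 0 h and at 7.3 to 22.3 FPKM at 24 h. The lowest were *REPS1*° (-4.49 ± 0.77), *SCAMP3* (-3.92 ± 0.52), *JAKMIP2*° (-3.86 ± 0.86) and *RPS10-NUDT3*°† (-3.77 ± 1.05), and *STAB1*°†, at 5.01 to 23 FPKM at 0 h and listed at 0 at 24 h. Single genes of lipid metabolism passed without their lists: *ETFA* (1.61 ± 0.32), an electron carrier of fatty acid oxidation, and *ASAH1*° (1.10 ± 0.25), the lysosomal ceramidase, rose, while *ETFDH*° (-0.78 ± 0.17) and *APOA1*° (-0.86 ± 0.19) fell. *ACSL1*, an acyl-CoA synthetase, was listed at 0 in WT at 0 h and at 2.54 to 4.74 FPKM at 24 h. The ribosomal protein list was not called here (adjusted p = 0.265, lower; 0.241, higher, after quantile normalization). *RPS9P1* is a pseudogene and *RPS10-NUDT3* a read-through gene, whose call was also lost under both scalings. Calls concentrated by class: 104 protein-coding genes without opposite-strand overlap rose and 48 fell, against 76 and 203 with overlap and 35 and 149 antisense genes. With only genes that have no such overlap, a subset chosen after seeing the data, 116 were called (79 higher, 37 lower); the count was 334 without a variance trend, 355 in a fit of these groups alone, and 453 without WT 24 h replicate 3. Among genes with no opposite-strand overlap the call was lost for the lysosome (adjusted p = 0.233) list. Leaving out 1 library ended the call for the G2/M (highest adjusted p = 0.0753, without WT 0 h replicate 2) and hepatocyte identity (highest adjusted p = 0.0665, without WT 0 h replicate 3) lists. After quantile normalization the hepatocyte list was not called (adjusted p = 0.147).

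At 48 h WT cells showed more sterol synthesis and lysosomal transcripts and fewer G2/M transcripts than at 0 h; the G1/S list was not called (adjusted p = 0.179). *APOA2*, an apolipoprotein of high-density lipoprotein, went from 112 ± 26.4 to 455 ± 29.8 FPKM (SD, n = 4), a change of 2.04 ± 0.20. *MSMO1* (1.48 ± 0.23), *SQLE* (1.32 ± 0.27), *CYP51A1*° (1.32 ± 0.16) and *DHCR7* (1.28 ± 0.29), enzymes of cholesterol synthesis, rose, as did the lysosomal hydrolases *CTSD*° (1.88 ± 0.36), *CTSL* (1.72 ± 0.25), *HEXA*° (1.70 ± 0.31) and *NEU1* (1.63 ± 0.39). *TOP2A*† (-1.97 ± 0.53), *HMMR*°† (-2.52 ± 0.75), *NUSAP1*† (-1.38 ± 0.40) and *TPX2*† (-0.98 ± 0.28), genes of DNA topology and the mitotic spindle, fell. The stress genes *HERPUD1* (4.91 ± 0.84), *HSPA5* (1.13 ± 0.19), *ATF3*† (2.41 ± 0.64), *PPP1R15A* (1.96 ± 0.30) and *PSAT1* (1.37 ± 0.24) were again higher than at 0 h. limma called 1171 genes, 443 higher and 728 lower, and 746 changed at least 2-fold. The calls were 590 higher and 585 lower with median-of-ratios rescaling, and 544 and 390 with quantile normalization.

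By list, 9 of 25 cholesterol synthesis genes rose. Among the members 13 rose and 2 fell adjusted over the list alone (camera adjusted p = 2.88e-07). Lysosome and autophagy genes had 6 of 30 higher. For the list 12 rose adjusted over the list alone (camera adjusted p = 1.45e-06). Of 24 G2/M genes 4 fell. In that list 13 fell adjusted over the list alone (camera adjusted p = 2.18e-07). NRF2 genes had 5 of 23 higher, with *SRXN1* (2.13 ± 0.52), *AKR1C2*† (1.73 ± 0.46), *SLC7A11*° (1.16 ± 0.30) and *TXN* (0.95 ± 0.24). Of the members 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 5.59e-06). ATF4 targets had 5 of 25 higher. Of its members 9 rose adjusted over the list alone (camera adjusted p = 0.000551). NF-kB genes had 2 of 16 higher, *IL32*† (2.79 ± 0.84) and *CXCL5* (1.40 ± 0.28). Within the list 2 rose adjusted over the list alone (camera adjusted p = 0.00113). In the ER list 5 of 26 rose and 1 fell. Among the members 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00383; adjusted p = 0.0724 with an estimated correlation). Lipoprotein genes had 3 of 19 higher, with *LIPC*† (2.47 ± 0.65) and *APOB*°† (0.63 ± 0.17). For the list 3 rose adjusted over the list alone (camera adjusted p = 0.0405; adjusted p = 0.0724 with an estimated correlation). EMT and matrix genes had 1 of 14, *FN1* (0.84 ± 0.17). In that list 5 rose adjusted over the list alone (camera adjusted p = 0.0168). Biliary and progenitor markers, fixed as signs of another cell type, had 2 of 10 higher, *SOX4*° (1.47 ± 0.30) and *CD24* (1.43 ± 0.27). Of the members 2 rose adjusted over the list alone (camera adjusted p = 0.007).

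Ribosomal protein genes had 7 of 32 lower, led by *RPS15* (-1.58 ± 0.31), *RPS2* (-1.17 ± 0.26), *RPL13* (-1.05 ± 0.27) and *RPL35*° (-1.00 ± 0.22). Of its members 11 fell adjusted over the list alone (camera adjusted p = 0.00101). After quantile normalization the list had an adjusted p of 0.918. Of 13 mitochondrially encoded genes 9 rose and 4 fell, with the same 9 and 4 adjusted over the list alone (camera adjusted p = 0.000516; adjusted p = 0.236 with an estimated correlation). The 4 were *MT-CO1*, *MT-CO3*, *MT-ATP6* and *MT-ATP8*, listed at 0 in all WT libraries at 48 h, and with these included the list's median (2.29) and mean (-1.89) differ in sign. The highest folds by the rule were *CYSRT1* (6.33 ± 0.68), *HERPUD1* (4.91 ± 0.84), *SPINK1* (4.77 ± 1.11), *RNF224* (4.69 ± 0.20) and *AREG* (4.67 ± 0.65), with *TRAPPC6A*†, which was listed at 0 at 0 h; the lowest, apart from the mitochondrial zeros, were *NT5DC4*° (-7.22 ± 1.38) and *METTL26*, listed at 0 at 48 h. *CYSRT1* and *RNF224* are neighbours on the same strand of chromosome 9, and *RNF224* went from 6.69 ± 1.39 to 185 ± 35.9 FPKM (adjusted p = 7.72e-14). Among lipid genes, *CPT1A*† (1.84 ± 0.54), which controls fatty acid entry into mitochondria, *GPAT3* (2.99 ± 0.63), *SCD* (0.88 ± 0.15), *ELOVL5* (1.41 ± 0.31), *ETFA* (1.75 ± 0.32) and *ASAH1*° (1.95 ± 0.25) rose and *ETFDH*° (-1.15 ± 0.17) and *LPCAT3*° (-0.85 ± 0.13) fell; *ACSL1* was listed at 0 at 0 h and at 4.67 to 9.07 FPKM at 48 h. Liver proteins *TTR* (1.50 ± 0.36), *AMBP* (1.12 ± 0.15) and *ALB* (0.94 ± 0.24) rose and *CP*° (-0.75 ± 0.19) fell. With no call of their lists, hypoxia, glycolytic, oxidative and replication genes *PFKFB3*† (-2.08 ± 0.61), *LDHA*† (-0.63 ± 0.17), *ANKRD37*° (-0.93 ± 0.23), *ATP5F1B* (-0.91 ± 0.23), *MCM5*† (-2.99 ± 0.88) and *MCM3*† (-1.19 ± 0.35) fell. Protein-coding genes without overlap had 209 higher and 85 lower, those with overlap 130 and 345, and antisense genes 50 and 213; with only the genes that have no overlap 237 were called (169 higher, 68 lower). The count was 750 without a variance trend and 591 in a fit of these groups alone. Of list calls those lost among genes with no opposite-strand overlap were the EMT (adjusted p = 0.0699) list. Without 1 library the call was lost for the EMT (highest adjusted p = 0.0568, without WT 0 h replicate 1) and lipoprotein (highest adjusted p = 0.0828, without WT 0 h replicate 2 or 3 or WT 48 h replicate 1 or 2) lists.

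**Figure D2:**
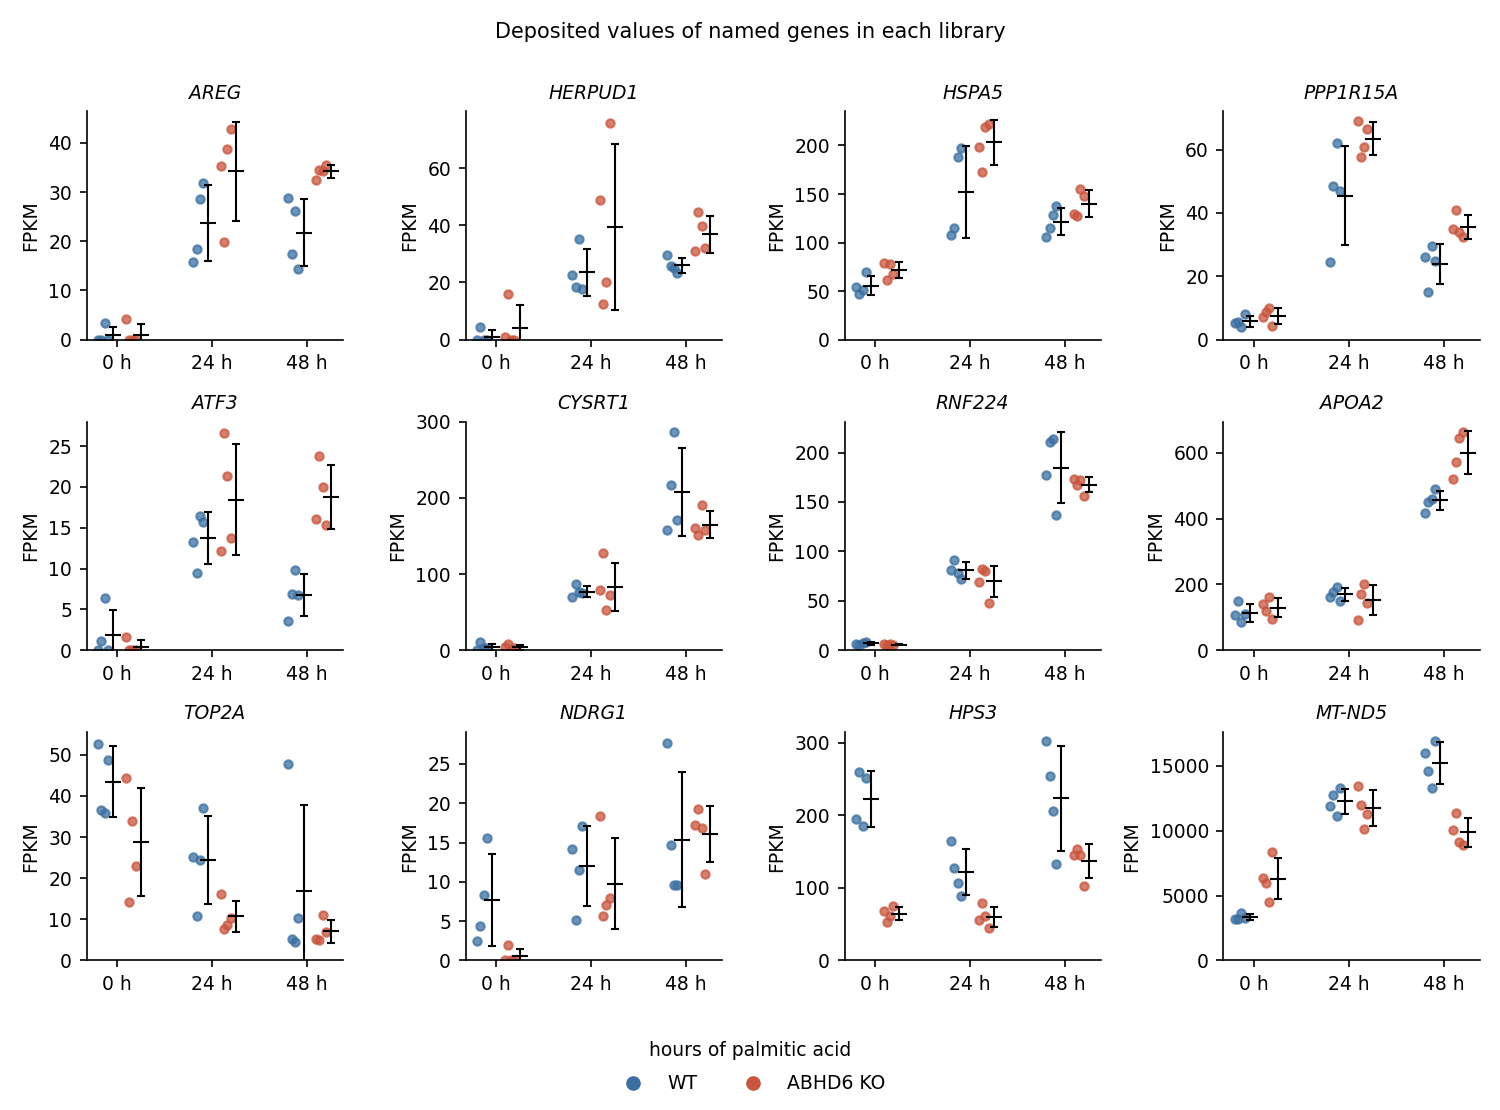
FPKM of 12 named genes in each library (y axis, linear from 0) by hours of palmitic acid and genotype. Points are libraries and bars the mean ± SD of 4, drawn no lower than 0; *AREG*, *CYSRT1* and *RNF224* are higher in all 16 libraries with palmitic acid than in the 8 without, and *TOP2A* in WT at 48 h includes 1 library at 47.8 FPKM against 4.54 to 10.4 in the other 3.

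The same comparison was made in the cells labelled KO. At 24 h *ATF3* (4.65 ± 0.64), *GDF15* (4.39 ± 1.07), *NUPR1*† (3.23 ± 0.93) and *CTH* (3.07 ± 0.68), targets of the integrated stress response factor ATF4, rose, with the ER genes *HERPUD1* (4.32 ± 0.84), *DNAJB9*°† (2.72 ± 0.76), *MANF* (1.99 ± 0.47) and *HYOU1*° (1.70 ± 0.29). The lipid droplet coat protein *PLIN2* rose by 1.93 ± 0.42, *ACSL1* by 2.35 ± 0.49 and *CPT1A*† by 1.94 ± 0.54. *AREG* (5.25 ± 0.65), *CXCL8*† (3.08 ± 0.79) and *IL32*† (3.03 ± 0.84), encoding a growth factor, a chemokine and a cytokine, also rose. *NDRG1*, a hypoxia-responsive gene, rose by 3.63 ± 0.58 from 0.503 ± 1.01 to 9.76 ± 5.81 FPKM (SD, n = 4). limma called 973 genes, 368 higher and 605 lower, 648 of them changed at least 2-fold. The calls were 467 higher and 496 lower with median-of-ratios rescaling, and 463 and 357 with quantile normalization.

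In the ER list 8 of 26 rose. Within the list 9 rose adjusted over the list alone (camera adjusted p = 2.69e-07). In the ATF4 list 7 of 25 rose. Among the members 10 rose adjusted over the list alone (camera adjusted p = 2.07e-06). Cholesterol synthesis genes had 7 of 25 higher, with *SC5D* (1.77 ± 0.45), *SQLE* (1.16 ± 0.27), *HMGCS1*° (1.08 ± 0.23) and *INSIG1* (0.98 ± 0.23). For the list 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00169). Immediate early genes had 4 of 18 higher. In that list 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00169); *KLF4* and *DUSP1* were listed at 0 at 0 h and reached 3.77 to 13 and 2.73 to 7.27 FPKM, and *KLF6* (1.78 ± 0.42) rose. NRF2 genes had 4 of 23 higher, *GCLC*° (2.93 ± 0.46), *NQO1*°† (1.47 ± 0.40), *TXNRD1* (0.84 ± 0.20) and *FTH1*°† (0.66 ± 0.18). Of the members 5 rose adjusted over the list alone (camera adjusted p = 0.00169; adjusted p = 0.0681 with an estimated correlation). NF-kB genes had 3 of 16 higher, *CXCL5* (1.47 ± 0.28) among them. Of its members 5 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0377; adjusted p = 0.128 with an estimated correlation). Hypoxia and glycolysis genes had 2 of 20 higher, *NDRG1* and *KDM3A* (2.18 ± 0.47), and 1 lower, *SLC2A1*° (-2.86 ± 0.65). Within the list 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0187). Lysosome genes had 2 of 30 higher, *CTSA*°† (0.65 ± 0.18) and *SQSTM1*°† (0.61 ± 0.18). Among the members 3 rose adjusted over the list alone (camera adjusted p = 0.0377). Biliary and progenitor markers had 2 of 10 higher, *CD24* (1.40 ± 0.27) and *SOX4*° (1.34 ± 0.30). For the list 2 rose adjusted over the list alone (camera adjusted p = 0.0185).

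In KO at 24 h the G1/S and DNA replication list fell, with 2 of 24 lower, *MCM2*°† (-2.03 ± 0.57) and *MCM3* (-1.56 ± 0.35). In that list 2 fell adjusted over the list alone (camera adjusted p = 0.0039). The G2/M list also fell, with 2 of 24 lower, *CENPE* (-2.22 ± 0.55) and *AURKA*† (-1.60 ± 0.47). Of the members 2 fell adjusted over the list alone (camera adjusted p = 0.00579). Ribosomal protein genes had 4 of 32 lower, *RPS15* (-1.40 ± 0.31), *RPL32*°† (-1.02 ± 0.30) and *RPL35*° (-0.92 ± 0.22) among them. Of its members 2 rose and 10 fell adjusted over the list alone (camera adjusted p = 0.00254), with an adjusted p of 0.621 after quantile normalization. Acute phase genes had 1 of 11 lower, *FGB* (-0.78 ± 0.16). Within the list 2 fell adjusted over the list alone (camera adjusted p = 0.0459; adjusted p = 0.0667 with an estimated correlation). Of 13 mitochondrially encoded genes 12 rose and 1 fell, with the same 12 and 1 adjusted over the list alone (camera adjusted p = 1.48e-23), led by *MT-ATP8* (2.43 ± 0.23), *MT-ND1* (2.16 ± 0.15) and *MT-ND2* (1.86 ± 0.15), and *MT-CO1* was listed at 0 in all 4 libraries. The highest folds by the rule were *AREG* (5.25 ± 0.65), *CYSRT1* (4.83 ± 0.68), *ATF3* (4.65 ± 0.64) and *RPS9P1*° (4.60 ± 0.86), and *LILRB3* and *MATN1*°, listed at 0 at 0 h and at 11.8 to 37.7 and 6.26 to 22.6 FPKM; the lowest were *RPS21P4*°† (-6.32 ± 1.82), *FANCD2OS*°† (-5.30 ± 1.34), *HMGN2P5*† (-5.04 ± 1.27) and *NT5DC4*°† (-4.71 ± 1.38) and *RSL24D1P6*, listed at 0 at 24 h. Other lipid and liver genes that passed were *ETFA* (1.39 ± 0.32), higher, and *ETFDH*° (-0.70 ± 0.17), *FADS1*° (-0.98 ± 0.17), *APOA1*° (-1.57 ± 0.19) and *ASGR2*† (-1.12 ± 0.29), lower. *RPS9P1*, *RPS21P4*, *HMGN2P5* and *RSL24D1P6* are pseudogenes. Protein-coding genes without overlap had 171 higher and 73 lower, those with overlap 107 and 292, and antisense genes 44 and 173; with only the genes that have no overlap 206 were called (142 higher, 64 lower). The count was 639 without a variance trend and 617 in a fit of these groups alone. Among genes with no opposite-strand overlap the call was lost for the lysosome (adjusted p = 0.225), NRF2 (adjusted p = 0.219) and biliary (adjusted p = 0.0764) lists. Leaving out 1 library ended the call for the acute phase (highest adjusted p = 0.111, without KO 0 h replicate 0, 2 or 3 or KO 24 h replicate 0, 1 or 3), lysosome (highest adjusted p = 0.0795, without KO 0 h replicate 1 or KO 24 h replicate 2) and NF-kB (highest adjusted p = 0.144, without KO 0 h replicate 0 or KO 24 h replicate 1 or 3) lists. The acute phase list was not called after median-of-ratios rescaling (adjusted p = 0.0692) or quantile normalization (0.227), nor the NF-kB list after quantile normalization (0.0501).

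After 48 h KO cells had 1695 calls, the most of the 11 comparisons. *APOA2* went from 129 ± 29 to 601 ± 65.7 FPKM (SD, n = 4), a change of 2.24 ± 0.20, and the sterol enzymes *SC5D* (2.65 ± 0.45), *MSMO1* (1.97 ± 0.23) and *HMGCS1*° (1.72 ± 0.23) rose. The ATF4 targets *ATF3* (4.72 ± 0.64), *GDF15* (4.09 ± 1.07), *NUPR1* (3.54 ± 0.93) and *PPP1R15A* (2.22 ± 0.30) and the oxidative stress genes *GCLC*° (2.50 ± 0.46), *NQO1*° (2.16 ± 0.40), *AKR1C2* (1.83 ± 0.46) and *SLC7A11*° (1.42 ± 0.30) were higher than at 0 h. *CDC20* (-2.71 ± 0.66), *KIF20A*°† (-2.56 ± 0.73), *CENPE* (-2.19 ± 0.55) and *TOP2A*† (-1.91 ± 0.53), which act in mitosis, and *MCM2*° (-2.09 ± 0.57), *MCM3* (-1.66 ± 0.35), *RRM2* (-1.26 ± 0.29) and *TYMS*° (-0.87 ± 0.22), which act in DNA replication, fell. *NDRG1* rose by 4.44 ± 0.58. limma called 1695 genes, 587 higher and 1108 lower, 1212 of them changed at least 2-fold. The calls were 813 higher and 849 lower with median-of-ratios rescaling, which moved the median of all genes by 0.105, and 747 and 677 with quantile normalization.

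Cholesterol synthesis had 12 of 25 genes higher and 1 lower. Among the members 13 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.98e-09). Fatty acid synthesis had 2 of 18 higher, *ACSS2*† (2.11 ± 0.61) and *SCD* (1.08 ± 0.15). For the list 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0146). NRF2 genes had 9 of 23 higher. In that list 14 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.98e-09). ATF4 targets had 8 of 25 higher. Of the members 11 rose adjusted over the list alone (camera adjusted p = 4.39e-08). ER genes had 4 of 26 higher and 1 lower, with *HERPUD1* (4.53 ± 0.84), *DNAJB9*° (2.95 ± 0.76) and *HSPA5* (0.97 ± 0.19). Of its members 13 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000107). Lysosome genes had 7 of 30 higher, *NPC2*°† (3.95 ± 1.12), *NEU1* (2.31 ± 0.39), *HEXA*° (1.79 ± 0.31) and *LAMP2* (1.71 ± 0.44) among them. Within the list 9 rose adjusted over the list alone (camera adjusted p = 4.5e-05). NF-kB genes had 3 of 16 higher, with *IL32* (4.20 ± 0.84) and *CXCL5* (1.18 ± 0.28) and *IL1B*, listed at 0 at 0 h and at 2.04 to 7.51 FPKM. Among the members 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000571). Immediate early genes had 5 of 18 higher, with *BTG2* (2.59 ± 0.57). For the list 5 rose adjusted over the list alone (camera adjusted p = 0.00123). Apoptosis regulators had 2 of 19 higher, *BMF*° (2.56 ± 0.58) and *PMAIP1* (1.47 ± 0.39), both pro-apoptotic. In that list 3 rose adjusted over the list alone (camera adjusted p = 0.0146). EMT and matrix genes had 2 of 14 higher, *FN1*† (0.58 ± 0.17) among them. Of the members 4 rose adjusted over the list alone (camera adjusted p = 0.0204). Biliary and progenitor markers had 3 of 10 higher, *SPP1*† (2.58 ± 0.80), *CD24* (1.98 ± 0.27) and *SOX4*° (1.48 ± 0.30). Of its members 3 rose adjusted over the list alone (camera adjusted p = 0.00153).

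G2/M genes had 7 of 24 lower. Within the list 13 fell adjusted over the list alone (camera adjusted p = 2.45e-07). G1/S genes had 4 of 24 lower. Among the members 4 fell adjusted over the list alone (camera adjusted p = 0.000611). Hepatocyte identity genes had 5 of 25 higher, *ARG1* (2.93 ± 0.82), *TTR* (1.52 ± 0.36) and *AMBP* (1.25 ± 0.15) among them, and 1 lower, *ASGR2*† (-0.94 ± 0.29). For the list 8 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0146; adjusted p = 0.102 with an estimated correlation). Of 13 mitochondrially encoded genes 12 rose and 1, *MT-CO1*, was listed at 0 after palmitic acid, with the same 12 and 1 adjusted over the list alone (camera adjusted p = 1.62e-19). The highest folds by the rule were *CYSRT1* (5.88 ± 0.68), *AREG* (5.31 ± 0.65), *SMIM26* (4.83 ± 1.21) and *RNF224* (4.78 ± 0.20), with *NPM2* and *RPL35P2*°, both listed at 0 at 0 h; the lowest were *FANCD2OS*° (-5.35 ± 1.34), *RPL29P23*° (-4.89 ± 1.10) and *PMCH*° (-4.64 ± 0.62) and *MYCNOS*° and *ID2*°, both listed at 0 at 48 h. *ID2*, an inhibitor of basic helix-loop-helix factors, lay at 5.52 to 24.2 FPKM in KO at 0 h. Of lipid genes *ACSL1* (3.14 ± 0.49), *CPT1A* (2.28 ± 0.54), *PLIN2* (2.17 ± 0.42), *GPAT3* (2.32 ± 0.63), *ETFA* (1.36 ± 0.32), *ASAH1*° (1.47 ± 0.25) and *PLD3*° (1.70 ± 0.44) rose and *ETFDH*° (-1.23 ± 0.17), *CIDEB*° (-0.79 ± 0.13), *APOA1*° (-1.24 ± 0.19) and *LPCAT3*° (-0.77 ± 0.13) fell, and *CES1* was listed at 0 at 0 h and at 1.63 to 10.2 FPKM. The ribosomal protein list was not called (adjusted p = 0.221, lower) and was higher after quantile normalization (adjusted p = 0.016). Protein-coding genes without overlap had 317 higher and 128 lower, those with overlap 172 and 516, and antisense genes 48 and 313; with only the genes that have no overlap 402 were called (274 higher, 128 lower). Of list calls those lost among genes with no opposite-strand overlap were the apoptosis (adjusted p = 0.361) list.

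**Figure D3:**
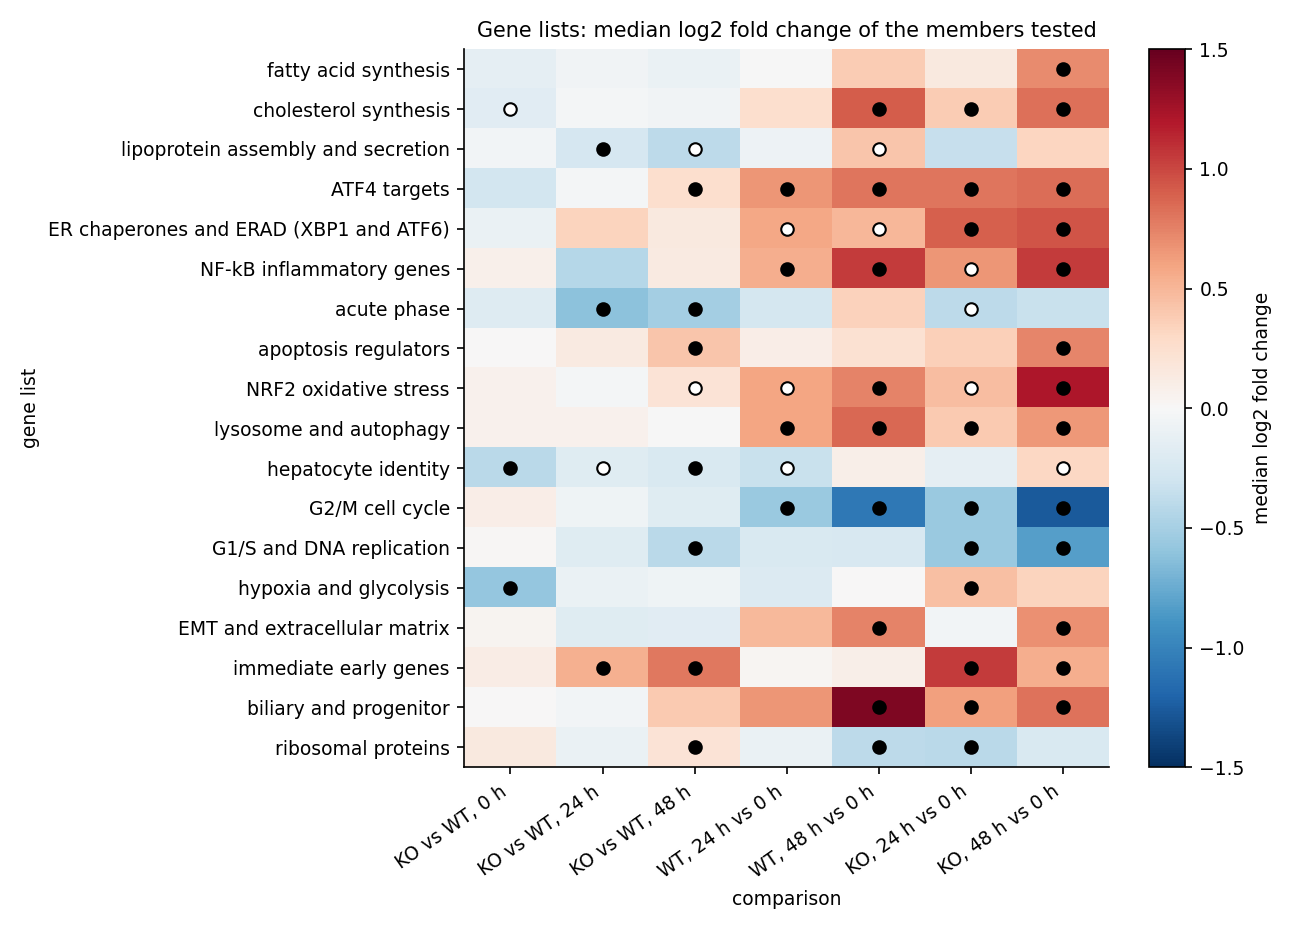
Median log2 fold change of the tested members (colour) of the gene lists with a call in at least 1 of 7 comparisons. Filled circles mark a camera adjusted p under 0.05 that held with an estimated correlation and open circles one that did not; the ATF4, NRF2, ER, NF-kB and lysosome lists were higher and G2/M lower in all 4 comparisons with 0 h. The mitochondrially encoded list is left out.

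Between 24 h and 48 h of palmitic acid, few single genes passed but several lists moved in both genotypes. *APOA2* rose by 1.43 ± 0.20 in WT (adjusted p = 0.00154) and 2.03 ± 0.20 in KO (adjusted p = 7.12e-06), and *AMBP*, a plasma protein precursor, by 0.81 ± 0.15 and 0.84 ± 0.15. Cholesterol synthesis genes rose as a list in WT (1 of 25 passing, 9 rose adjusted over the list alone, camera adjusted p = 1.28e-09) and in KO (2, with *MSMO1* (1.13 ± 0.23), 10 rose adjusted over the list alone, camera adjusted p = 1.31e-08). Hepatocyte identity had 1 of 25 higher in WT (5 rose adjusted over the list alone, camera adjusted p = 1.28e-09) and 2 in KO, with *TF* (0.69 ± 0.16) (6 rose adjusted over the list alone, camera adjusted p = 9.47e-07). Fatty acid synthesis had 0 of 18 in WT (2 rose adjusted over the list alone, camera adjusted p = 0.000462) and 1 in KO, *SCD* (0.74 ± 0.15) (4 rose adjusted over the list alone, camera adjusted p = 1.12e-05). Lysosome genes had 0 of 30 in WT (3 rose adjusted over the list alone, camera adjusted p = 0.000652) and 2 in KO, *CTSD*° (1.59 ± 0.36) and *CTSL* (1.14 ± 0.25) (5 rose adjusted over the list alone, camera adjusted p = 0.000464). Lipoprotein genes had 1 of 19, *APOA2*, in WT (3 rose adjusted over the list alone, camera adjusted p = 0.000817) and in KO (1 rose adjusted over the list alone, camera adjusted p = 0.000225). G2/M genes fell in WT (1 of 24, *CCNB1* (-1.59 ± 0.32), 1 fell adjusted over the list alone, camera adjusted p = 1.36e-05) and in KO (0 passing, 1 fell adjusted over the list alone, camera adjusted p = 0.000137). With 1 library left out the calls of *CTSD* and *TF* in KO and *CCNB1* in WT were lost in 8 of 8 fits, *CTSL* in 6, *SCD* in 5 and *MSMO1* in 4, and in WT *AMBP* in 5 and *MT-ND2* in 6.

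EMT and matrix genes were higher as a list in WT (0 passed adjusted over the list alone, camera adjusted p = 0.01) and KO (1 rose adjusted over the list alone, camera adjusted p = 0.00725) with 0 of 14 passing over all genes in either. Acute phase genes were higher in WT (1 rose adjusted over the list alone, camera adjusted p = 0.0384; adjusted p = 0.0531 with an estimated correlation) and in KO (4 rose adjusted over the list alone, camera adjusted p = 0.0424; adjusted p = 0.0638 with an estimated correlation), also with 0 of 11 passing. In WT alone the interferon list was called, higher, with 0 of 9 (0 passed adjusted over the list alone, camera adjusted p = 0.0328; adjusted p = 0.0506 with an estimated correlation), and in KO the NRF2 list, higher, with 0 of 23 (4 rose adjusted over the list alone, camera adjusted p = 9.47e-07) and the NF-kB list with 1 of 16, *ICAM1*° (1.40 ± 0.27) (2 rose adjusted over the list alone, camera adjusted p = 0.0427; adjusted p = 0.171 with an estimated correlation); the difference between genotypes was not tested for this interval. Ribosomal protein genes were lower in WT (2 fell adjusted over the list alone, camera adjusted p = 0.000953), with an adjusted p of 0.0797 after quantile normalization, and higher in KO (0 passed adjusted over the list alone, camera adjusted p = 0.0407; adjusted p = 0.0805 with an estimated correlation), with 0 of 32 passing in either. limma called 21 genes in WT, 10 higher and 11 lower, and 11 changed at least 2-fold. Of the 21, *MT-CO3*, *MT-ATP6* and *MT-ATP8* were listed at 0 at 48 h, and *MT-ND2* (0.76 ± 0.15) rose. In KO 89 were called, 19 higher and 70 lower, and 41 changed at least 2-fold; of the lower ones 26 were antisense and 33 were protein-coding with opposite-strand overlap. The share of higher calls moved with scaling: 29 higher and 14 lower in WT with quantile normalization, and in KO 33 and 60 with median-of-ratios rescaling and 54 and 52 with quantile normalization. The WT count was 4 without a variance trend, 12 in a fit of these groups alone, 6 without WT 24 h replicate 2, 7 without WT 24 h replicate 3 and 9 without WT 48 h replicate 0; the KO count was 10 without a variance trend, 159 with array weights, and 47, 57, 56 and 52 without KO 24 h replicate 0 and KO 48 h replicates 1, 2 and 3. Among genes with no opposite-strand overlap in WT the call was lost for the EMT (adjusted p = 0.623) and interferon (adjusted p = 0.123) lists. Leaving out 1 library in WT ended the call for the acute phase (highest adjusted p = 0.173, without WT 24 h replicate 0 or 2 or WT 48 h replicate 1) and interferon (highest adjusted p = 0.173, without WT 24 h replicate 2 or WT 48 h replicate 0, 1 or 2) lists. Of list calls in KO those lost among genes with no opposite-strand overlap were the NF-kB (adjusted p = 0.341) and ribosomal protein (adjusted p = 0.349) lists. Without 1 library in KO the call was lost for the acute phase (highest adjusted p = 0.121, without KO 24 h replicate 0, 1 or 3 or KO 48 h replicate 0 or 2), NF-kB (highest adjusted p = 0.249, without KO 24 h replicate 0, 1 or 2 or KO 48 h replicate 0 or 3) and ribosomal protein (highest adjusted p = 0.14, without KO 24 h replicate 0 or 1 or KO 48 h replicate 0 or 3) lists. The interferon list in WT was not called after quantile normalization (adjusted p = 0.0646), nor the acute phase list with the replicate number as a block (0.0504).

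KO and WT cells in basal medium were compared to find differences before any palmitic acid. *NDRG1* was lower in KO (-3.17 ± 0.58, adjusted p = 0.0169), at 0.503 ± 1.01 FPKM against 7.71 ± 5.82 in WT (SD, n = 4), as was *ADGRG5* (-1.65 ± 0.30), an adhesion G protein-coupled receptor. *HPS3*°, whose product takes part in forming lysosome-related organelles, was at 64.5 ± 9.26 against 222 ± 38.2 FPKM (-1.77 ± 0.24, adjusted p = 0.000747); its exons overlap the ceruloplasmin gene *CP*°. *NQO1*° (-2.05 ± 0.40) and *CSNK1D*° (-1.77 ± 0.29), a quinone reductase and a casein kinase, were lower and overlap *AC092115.2*° and *AC132872.4*. *AKR7A2*, an aldehyde reductase, lay at 2.41 to 10.6 FPKM in WT and was listed at 0 in all KO libraries. Of mitochondrially encoded genes *MT-ND3* (0.96 ± 0.15), *MT-ND5* (0.88 ± 0.13) and *MT-CO3* (0.71 ± 0.12) were higher in KO.

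Hypoxia and glycolysis genes were lower in KO at 0 h: 1 of 20, *NDRG1*, passed over all genes, 4 fell adjusted over the list alone, and 18 had a lower mean (camera adjusted p = 3.26e-08); members that did not pass include *PFKFB3* (-2.90 ± 0.61), *LDHA* (-0.59 ± 0.17) and *ENO1*° (-0.58 ± 0.19), with adjusted p of 0.0709, 0.35 and 0.44. Hepatocyte identity genes were lower as a list, with 0 of 25 passing, 5 fell adjusted over the list alone, and 24 with a lower mean (camera adjusted p = 3.55e-08), *TF*, transferrin, at -0.72 ± 0.16 (adjusted p = 0.0768). Cholesterol synthesis genes were lower with 0 of 25 passing. In that list 0 passed adjusted over the list alone (camera adjusted p = 0.00261; adjusted p = 0.108 with an estimated correlation). Mitochondrially encoded genes had 3 of 13 higher. Of the members 6 rose adjusted over the list alone (camera adjusted p = 3.55e-08; adjusted p = 0.189 with an estimated correlation). limma called 17 genes, 4 higher and 13 lower, 13 of them changed at least 2-fold; 6 of those lower are antisense genes. The count was 36 without WT 0 h replicate 0, 8 without a variance trend and 7 among genes with no opposite-strand overlap (4 higher, 3 lower). A fit of these groups alone also called 17, of which 4 were among these 17, and of the 9 genes selected by the rule only *HPS3* kept its call there. *NQO1*° was not called without any one of the 8 libraries, *NDRG1* without WT replicates 2 or 3 or KO replicates 0, 2 or 3, and *ADGRG5* without WT replicate 1. Among genes with no opposite-strand overlap the call was lost for the cholesterol synthesis (adjusted p = 0.141) list. Leaving out 1 library ended the call for the cholesterol synthesis (highest adjusted p = 0.104, without WT 0 h replicate 3) list.

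After 24 h of palmitic acid 2 genes differed between KO and WT, and both are named because the count is small. *SCAMP3*, a carrier protein of post-Golgi membranes, was higher in KO (3.15 ± 0.52, adjusted p = 0.0339), at 4.74 to 7.43 FPKM against 0 to 2.28 in WT; the call was lost without any one of 7 of the 8 libraries. *AC092115.2*°, which lies antisense to *NQO1*° and was chosen after its values were seen, was lower (-1.03 ± 0.16, adjusted p = 0.0339). Acute phase genes were lower in KO as a list with 0 of 11 passing, 4 fell adjusted over the list alone, and 10 with a lower mean (camera adjusted p = 0.000124); the fibrinogen genes *FGB* (-0.65 ± 0.16) and *FGA* (-0.94 ± 0.30) did not pass alone (adjusted p = 0.434 and 0.744). Lipoprotein genes were lower with 0 of 19 passing. Of its members 1 fell adjusted over the list alone (camera adjusted p = 0.00322), *APOA1*° at -0.88 ± 0.19 (adjusted p = 0.276). Immediate early genes were higher with 0 of 18 passing. Within the list 0 passed adjusted over the list alone (camera adjusted p = 0.00495). Hepatocyte identity genes were lower with 0 of 25 passing. Among the members 4 fell adjusted over the list alone (camera adjusted p = 0.0148; adjusted p = 0.232 with an estimated correlation). Both calls changed at least 2-fold. The count was 5 under median-of-ratios or quantile scaling (2 higher, 3 lower), 13 in a fit of these groups alone (0 of them among these 2), 1 with a pseudocount of 1, 0 with the replicate number as a block and 0 without WT 24 h replicate 0 or 2 or KO 24 h replicate 0, 2 or 3. Of list calls those lost among genes with no opposite-strand overlap were the immediate early (adjusted p = 0.0967) list. Without 1 library the call was lost for the hepatocyte identity (highest adjusted p = 0.15, without WT 24 h replicate 0 or KO 24 h replicate 0 or 3) and lipoprotein (highest adjusted p = 0.0537, without WT 24 h replicate 0) lists.

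After 48 h the immediate early and ribosomal protein lists were higher in KO than in WT and acute phase and hepatocyte lists lower. Immediate early genes had 0 of 18 passing and 17 with a higher mean. For the list 0 passed adjusted over the list alone (camera adjusted p = 1.9e-05), with *DUSP1* (1.88 ± 0.76) and *ATF3* (1.46 ± 0.64) not passing (adjusted p = 0.66 and 0.709). Ribosomal protein genes had 29 of 32 with a higher mean, 0 passing. In that list 2 rose adjusted over the list alone (camera adjusted p = 1.48e-05). Acute phase genes had 11 of 11 with a lower mean, 0 passing. Of the members 2 fell adjusted over the list alone (camera adjusted p = 0.000363). Hepatocyte identity genes had 21 of 25 with a lower mean, 0 passing. Of its members 0 passed adjusted over the list alone (camera adjusted p = 0.000893). ATF4 targets (0 passed adjusted over the list alone, camera adjusted p = 0.0017), apoptosis regulators (0 passed adjusted over the list alone, camera adjusted p = 0.0132) and NRF2 genes (1 rose adjusted over the list alone, camera adjusted p = 0.00749; adjusted p = 0.197 with an estimated correlation) were higher, and G1/S genes (0 passed adjusted over the list alone, camera adjusted p = 0.00615) and lipoprotein genes (1 fell adjusted over the list alone, camera adjusted p = 0.0272; adjusted p = 0.057 with an estimated correlation) lower, each with 0 passing over all genes. Single genes called were *FBXO38* (2.06 ± 0.40), an F-box protein, *MMEL1*° (-1.72 ± 0.31) and *ADGRG5* (-1.54 ± 0.30), a membrane metalloendopeptidase that overlaps *PRXL2B* and the receptor named above, and *ID2*°, at 6.02 to 10.6 FPKM in WT and listed at 0 in KO. Among genes with no opposite-strand overlap the call was lost for the apoptosis (adjusted p = 0.342), G1/S (adjusted p = 0.131) and lipoprotein (adjusted p = 0.0901) lists. Leaving out 1 library ended the call for the apoptosis (highest adjusted p = 0.059, without WT 48 h replicate 3), lipoprotein (highest adjusted p = 0.155, without WT 48 h replicate 3 or KO 48 h replicate 0 or 2) and NRF2 (highest adjusted p = 0.066, without WT 48 h replicate 1) lists. The lipoprotein call was also lost without genes that have a group at 0 (adjusted p = 0.0572).

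*MT-CO3*, *MT-ATP6* and *MT-ATP8* were listed at 0 in WT at 48 h and at 3955 to 5169, 5570 to 6952 and 36519 to 40147 FPKM in KO, so no fold is given; over the 8 other genes of the mitochondrial list that were never at 0, *MT-ND6* left out, the median was -0.46. limma called 11 genes, 4 higher and 7 lower, 7 of them changed at least 2-fold; 4 have a group at 0. Without such genes, left out after seeing the data, 2 were called (0 higher, 2 lower), and 3 among genes with no opposite-strand overlap (3 higher, 0 lower, these being *MT-CO3*, *MT-ATP6* and *MT-ATP8*). The count was 33 without WT 48 h replicate 3 and 6 without WT 48 h replicate 0, WT 48 h replicate 2 or KO 48 h replicate 2, 27 with the replicate number as a block, 20 with array weights, 4 without a variance trend, 7 with a pseudocount of 0.1 and 17 in a fit of these groups alone (5 of them among these 11). With median-of-ratios rescaling 5 were higher and 16 lower, and with quantile normalization 8 and 18. *FBXO38* was not called without any one of the 8 libraries, *ADGRG5* without any of 6 and *MMEL1*° without any of 5, and they were lost under 6, 6 and 3 alternatives.

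Whether KO and WT cells responded differently to palmitic acid was tested as the difference of the 2 responses. At 24 h limma called 0 genes; 950 had an unadjusted p under 0.05, a fit of these groups alone called 2, and 2, 1 and 1 were called without KO 0 h replicate 0, KO 0 h replicate 2 and WT 24 h replicate 3. Hypoxia and glycolysis genes had a higher response in KO, with 0 of 20 passing, 3 rose adjusted over the list alone, and 18 higher (camera adjusted p = 6.6e-06), among them *NDRG1* (2.86 ± 0.82), *KDM3A* (2.39 ± 0.67) and *PFKFB3* (2.76 ± 0.86), which did not pass (adjusted p = 0.728, 0.7 and 0.776). This list was lower in KO than in WT at 0 h, the shared baseline of the difference. The mitochondrially encoded list had a lower response in KO with 0 of 13 passing. It was higher in KO at 0 h, and over 8 genes never at 0 the median difference between KO and WT was 0.55 at 0 h and -0.05 at 24 h. Within the list 5 fell adjusted over the list alone (camera adjusted p = 1.04e-07; adjusted p = 0.313 with an estimated correlation). At 48 h 9 genes were called, 3 higher and 6 lower, 7 of them changed at least 2-fold. *MT-ND5* (-1.51 ± 0.18), *MT-ND3* (-1.38 ± 0.21) and *MT-ND4* (-1.15 ± 0.21), subunits of respiratory complex I, responded less in KO. *MT-CO3*, *MT-ATP6*, *MT-ATP8* and *ID2*° were listed at 0 in a group. The antisense genes *AC009630.2*° (-0.98 ± 0.15) and *AL049830.3*° (-0.92 ± 0.17), chosen after their values were seen, overlap *GINS4* and *COCH*. Without genes that have a group at 0, 3 were called (0 higher, 3 lower), and 4 without a variance trend. The *MT-ND3* call was lost in a fit of these groups alone and without a variance trend, and *MT-ND5* without a variance trend. The *MT-ND4* call was lost without any one of 12 of the 16 libraries, under both scalings, without a filter, without genes at 0 in a group, and in the same fits as *MT-ND3*. The *ID2*° call was lost without any one of 10 of the 16, with a pseudocount of 1 and with the replicate number as a block.

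Of the lists at 48 h, hypoxia and glycolysis (18 of 20 higher, 1 rose adjusted over the list alone, camera adjusted p = 0.00881) and immediate early genes (14 of 18 higher, 0 passed adjusted over the list alone, camera adjusted p = 0.0107) had a higher response in KO. ATF4 targets (0 passed adjusted over the list alone, camera adjusted p = 0.0182; adjusted p = 0.123 with an estimated correlation), apoptosis regulators (0 passed adjusted over the list alone, camera adjusted p = 0.0362; adjusted p = 0.0741 with an estimated correlation) and NRF2 genes (0 passed adjusted over the list alone, camera adjusted p = 0.0362; adjusted p = 0.353 with an estimated correlation) were higher and G1/S genes lower (0 passed adjusted over the list alone, camera adjusted p = 0.0423; adjusted p = 0.132 with an estimated correlation), each with 0 passing over all genes. The responses of WT and KO overlapped. At 24 h 127 genes rose and 305 fell in both, against 5.38 and 15.7 for independent lists, and 0 were called in opposite directions; at 48 h the numbers were 216 and 563, against 15.1 and 46.8, with 4 opposite. The log2 fold changes of all tested genes correlated at 0.321 (24 h) and 0.379 (48 h) across genes, which are not independent replicates, and at 0.638 and 0.673 over genes with mean FPKM of at least 20, a floor chosen after seeing the data. The KO effects at different times correlated at 0.0117 (0 h and 24 h), 0.0186 (0 h and 48 h) and 0.0153 (24 h and 48 h). Of list calls those lost among genes with no opposite-strand overlap were the apoptosis (adjusted p = 0.626), ATF4 (adjusted p = 0.242), G1/S (adjusted p = 0.318), immediate early (adjusted p = 0.242) and NRF2 (adjusted p = 0.626) lists. Without 1 library the call was lost for the apoptosis (highest adjusted p = 0.071, without WT 0 h replicate 0, KO 0 h replicate 1 or 3 or WT 48 h replicate 1 or 3), ATF4 (highest adjusted p = 0.071, without WT 0 h replicate 0, KO 0 h replicate 1 or 3 or WT 48 h replicate 1), G1/S (highest adjusted p = 0.101, without WT 0 h replicate 0, 1 or 2, KO 0 h replicate 0 or 3, WT 48 h replicate 1 or 2 or KO 48 h replicate 0 or 1) and NRF2 (highest adjusted p = 0.309, without WT 0 h replicate 0, KO 0 h replicate 1, 2 or 3, WT 48 h replicate 1 or KO 48 h replicate 3) lists.

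Camera called 95 of 330 list tests, 30 lists in 11 comparisons, and 70 of the 95 held with an estimated correlation; the 25 others are given with that value above. Lists with no call were monoacylglycerol and endocannabinoid genes, the class to which *ABHD6* belongs (lowest adjusted p = 0.101 over the comparisons, at most 1 of 12 members called), PPAR alpha targets (0.0559, at most 3 of 16), mitochondrial beta oxidation (0.306, at most 4 of 19), triglyceride synthesis and lipid droplets (0.0981, at most 3 of 27), phospholipid and sphingolipid metabolism (0.221, at most 3 of 30), nuclear OXPHOS subunits (0.338, at most 3 of 35) and metallothioneins (0.355, 0 of 2). Markers of other cell types were also not called: stellate and fibroblast (lowest adjusted p = 0.549, 0 of 3 called), immune (0.179, at most 1 of 5) and endothelial (0.338, 0 of 2). A list's median, mean and test differed in sign in 60 of the 330 tests, of which 1 was called, the mitochondrial list in WT at 48 h.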

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

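The tests in this part were chosen after the results they bear on were seen, except the correlation across antisense pairs and the tests of the interaction. Genes annotated as antisense stood above the genes they overlap. The antisense gene was higher in 82.4% of 512 pairs, with a median log2 ratio of 4.08, a size that argues against counting without regard to strand, which would put both members of a pair at similar values. What stays open is that reads of the directional kit may have been counted with the opposite strand setting, in which case a listed antisense gene would carry most reads of its partner. *MT-ND6*, which lies on the other mitochondrial strand from *MT-CO2*, averaged 20502 FPKM in WT at 0 h against 1083. No biological explanation was tested.

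After palmitic acid, falls concentrated in antisense genes and in genes with opposite-strand exon overlap. Deeper libraries at 24 h and 48 h are argued against by the 371 antisense genes at 100 FPKM or more, whose median log2 change in WT at 48 h was -0.51 (95% bootstrap interval -0.58 to -0.47) and not near 0. A larger share of reads on the other strand at 24 h and 48 h was not settled: over 85 pairs the partner's log2 change exceeded that of the antisense gene by a median of 0.44, in 63 of the 85, but the partners did not rise (median -0.05, antisense genes -0.58), so this value restates the fall and does not bear on its cause. A response of the genes on the other strand also stays open: the members of a pair correlated at 0.169 across pairs, between the bounds set beforehand for WT at 48 h, so this test left it undecided; the other 3 comparisons with 0 h gave 0.0929 (WT at 24 h), 0.0918 and 0.0990 (KO at 24 h and 48 h), under the lower bound.

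Mitochondrially encoded genes rose after palmitic acid while *MT-CO1* was listed at 0 in all 16 treated libraries, and *MT-CO3*, *MT-ATP6* and *MT-ATP8* in all 4 of WT at 48 h. Failed estimates by the quantification software may lie behind these zeros. Each of the 4 genes had the worth of at least 100 fragments in all libraries of the groups not at 0. The lowest was 174 fragments, for *MT-CO1* at 0 h. A larger share of reads on the other strand as the whole cause of the rise is argued against by *MT-ND6*, which lies on the other strand and rose by 0.86 in WT at 24 h, beside a median of 2.02 for 8 other genes. A response of mitochondrial transcripts to palmitic acid was not tested apart from these, and the zeros enter the differences between KO and WT at 48 h.

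In the interaction at 48 h, the difference between the KO and WT responses had an adjusted p of 2.44e-24 for *MT-CO3*, 5.36e-21 for *MT-ATP8* and 1.95e-19 for *MT-ATP6*, all listed at 0 in WT at 48 h. It was 0.000129 for *MT-ND5*, 0.00413 for *MT-ND3* and for *AC009630.2*, 0.0297 for *ID2* and for *AL049830.3*, and 0.0319 for *MT-ND4*. Among lists it was 6.6e-06 for hypoxia and glycolysis and 1.04e-07 for the mitochondrially encoded genes at 24 h (0.313 with an estimated correlation). At 48 h it was 0.00881 for hypoxia and glycolysis, 0.0107 for immediate early genes, 0.0182 for ATF4 targets, 0.0362 for apoptosis regulators and for NRF2 genes, and 0.0423 for G1/S genes. With an estimated correlation these last 4 were not called (0.123, 0.0741, 0.353 and 0.132).

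A library stood apart from the other 3 of its group in 15 of 107 groups of values tested, where chance gives about 1 in 20 for continuous values. That rate does not hold where 3 libraries are at 0, as for *ABHD6*, *AREG*, *ATF3*, *NDRG1* and *HERPUD1* below, since any value above 0 then stands apart by construction, and no excess over chance is claimed. The summed FPKM of WT 48 h replicate 3 was 748252 against 917347 to 949068, and the fragments of KO 0 h replicate 1 were 505223 against 414265 to 418164. *ABHD6* was at 1.16 FPKM in WT 0 h replicate 0, 0.785 in WT 24 h replicate 0, 0.759 in KO 24 h replicate 3 and 0.846 in WT 48 h replicate 0, each against 0, and at 0 in KO 48 h replicate 3 against 0.693 to 0.771. *AREG* was at 3.45 FPKM in WT 0 h replicate 2 and 4.18 in KO 0 h replicate 0, and *ATF3* at 1.63 in KO 0 h replicate 0, each against 0. *HERPUD1* was at 4.31 FPKM in WT 0 h replicate 1 against 0 and at 15.9 in KO 0 h replicate 1 against 0 to 1.07. *NDRG1* was at 2.01 FPKM in KO 0 h replicate 1 against 0, *TOP2A* at 47.8 in WT 48 h replicate 0 against 4.54 to 10.4, and *HPS3* at 103 in KO 48 h replicate 3 against 146 to 154.

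Other splits of the same libraries were fitted on the groups compared alone, 35 for each pair of groups and 100 drawn for each interaction, and the counts below include the real split. For KO against WT, 5 splits gave as many calls as the real 17 at 0 h (highest other 21), 5 as the real 13 at 24 h (22) and 3 as the real 17 at 48 h (18), so chance was not excluded. In WT 1 split reached the real 355 at 24 h against 0 h (highest other 17) and 1 the real 591 at 48 h against 0 h (23). In KO 1 split reached the real 617 at 24 h (21), 1 the real 1439 at 48 h (14) and 1 the real 97 for 48 h against 24 h (17). Chance was excluded for these 5 counts. For WT at 48 h against 24 h, 13 splits reached the real 12 (highest other 20), and for the interaction at 24 h 46 reached the real 2 (7), so chance was not excluded. For the interaction at 48 h 1 split reached the real 8 (7), a margin of 1 call that left chance undecided. Of the 9 calls in the fit of all groups 3 are *MT-CO3*, *MT-ATP6* and *MT-ATP8*, 3 were called without genes at 0 in a group and as few as 6 without 1 library, and splits without such genes were not tested.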

How the results depend on the processing

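The tests without genes listed at 0 in a whole group, on genes with no opposite-strand overlap, over genes at 20 FPKM or more, and of lists after quantile normalization were chosen after seeing the data. No call of a gene or list named in the text became a call in the other direction, and robust variance and a filter at 2 FPKM moved no count by over 1.5 times. With quantile normalization the calls against 0 h turned from mostly lower to mostly higher (WT 296 higher and 248 lower at 24 h, 544 and 390 at 48 h; KO likewise), and the ribosomal protein list in KO at 48 h went from lower (adjusted p = 0.221) to higher (adjusted p = 0.016). Where a count moved by over 1.5 times the cause was not tested, except that the tests on fewer genes or fewer libraries have less to call by construction. Counts are of genes called, with those changed at least 2-fold given as second values. With a pseudocount of 0.1, KO against WT at 48 h had 7, and with a pseudocount of 1 KO against WT at 24 h had 1 and 1. Without a filter on low values the second value of KO against WT at 48 h was 11. With median-of-ratios rescaling, KO against WT had 5 and 5 at 24 h and 21 at 48 h. With quantile normalization these were 5 and 5, and 26, and WT at 48 h against 24 h had 43. In fits of the groups compared alone, KO against WT had 13 and 13 at 24 h and 17 and 16 at 48 h, WT had 355 and 207 at 24 h, 591 and 413 at 48 h and 12 for 48 h against 24 h, KO had 617 and 389 at 24 h, and the interaction at 24 h had 2 and 2. Without a variance trend KO against WT had 8 and 8 at 0 h and 4 and 4 at 48 h, WT 334 at 24 h, 750 at 48 h and 4 and 4 for 48 h against 24 h, KO 639 at 24 h and 10 and 10 for 48 h against 24 h, and the interaction at 48 h 4 and 4. With array weights KO against WT at 48 h had 20, and KO at 48 h against 24 h 159 and 68. Without genes listed at 0 in a whole group KO against WT at 48 h had 2 and 0, WT at 48 h against 24 h a second value of 5, and the interaction at 48 h 3 and 2. On genes with no opposite-strand overlap KO against WT had 7 and 4 at 0 h and 3 and 3 at 48 h, WT 116 and 97, 237 and 209, and 12 for 48 h against 24 h, and KO 206 and 182, 402 and 361, and 7 and 6 for 48 h against 24 h.

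Replicate numbers do not clearly pair the libraries: residuals of libraries with the same number correlated at -0.125 to 0.144 (mean 0.00852, against -0.00286 for other numbers), and 22 of 60 matched best with their own number. With the number as a block KO against WT had 24 calls at 0 h, 0 and 0 at 24 h and 27 at 48 h, WT and KO at 48 h against 24 h had 36 and 122, and the interaction at 48 h had 13. The correlation of the WT and KO responses was 0.351 at 24 h and 0.410 at 48 h with a pseudocount of 1, and 0.638 and 0.673 over genes at 20 FPKM or more. Over those genes the KO effects correlated at 0.0282 (0 h and 24 h), -0.0152 (0 h and 48 h) and 0.0800 (24 h and 48 h). With a pseudocount of 0.1 the difference in *ABHD6* was 1.47 for KO against WT at 48 h and 1.51 for KO at 48 h against 24 h. Against KO at 0 h, where all 4 libraries are at 0, it was 2.29, and 2.39 for the interaction at 48 h, values set by the pseudocount and not folds.

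With 1 library left out, KO against WT had 16 to 36 calls at 0 h (13 to 31 changed 2-fold), the highest without WT 0 h replicate 0. At 24 h it had 0 to 2 (0 to 2), with 0 without WT replicate 0 or 2 or KO replicate 0, 2 or 3. At 48 h it had 6 to 33 (4 to 14), with 6 without WT replicate 0 or 2 or KO replicate 2 and 33 without WT replicate 3. WT at 24 h had 453 to 684, the lowest without WT 24 h replicate 3. WT at 48 h against 24 h had 6 to 26 (5 to 13), with 6, 7 and 9 without WT 24 h replicate 2, WT 24 h replicate 3 and WT 48 h replicate 0. KO at 48 h against 24 h had 47 to 74 (25 to 40), with 47 without KO 24 h replicate 0 and 57, 56 and 52 without KO 48 h replicates 1, 2 and 3. The interaction had 0 to 2 (0 to 1) at 24 h, with 2, 1 and 1 without KO 0 h replicate 0, KO 0 h replicate 2 and WT 24 h replicate 3, and 6 to 13 (5 to 13) at 48 h, the highest without KO 0 h replicate 1 or 2. WT at 48 h had 887 to 1073, KO at 24 h 708 to 939, KO at 48 h 1347 to 1623, and the lists 87 to 98 calls, all within 1.5 times.

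Of the 95 list calls 25 were lost with an estimated correlation, 1 with median-of-ratios rescaling, 7 with quantile normalization, 1 with the replicate block, 1 without genes listed at 0 and 20 on genes with no opposite-strand overlap, and with a library left out 73 tests lost a call and 751 kept it. Some genes selected by the rule stayed called without any 1 library and in every alternative that tested them. WT had 24 of 62 at 24 h and 38 of 95 at 48 h, and KO 32 of 79 and 72 of 116. For 48 h against 24 h WT had 3 of 10 and KO 2 of 14. KO against WT had 1 of 9, 0 of 1 and 4 of 7 at 0 h, 24 h and 48 h. The interaction at 48 h had 3 of 7. The 1 at 0 h (*HPS3*) has an overlap and the 4 and 3 at 48 h a group at 0. The subsets without such genes left them out. Depth is a limit, since 1 fragment on a 2 kb transcript was worth 0.693 to 1.25 FPKM, the order of *ABHD6* values above 0. The strand setting is another (see above).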

Other observations

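The pairs of a gene and its opposite-strand partner in this part were chosen after their values were seen, 5 of 13 examined. *VIM-AS1*, at a mean of 2906 FPKM, overlaps *VIM*, the gene of the intermediate filament vimentin, at 18.2 FPKM. *VIM-AS1* was lower in KO than in WT at 0 h (log2 change -1.24, adjusted p = 0.00299), where *VIM* had -1.12 (adjusted p = 0.642). It rose by 2.13 and 1.79 in KO at 24 h and 48 h and by 1.12 and 0.71 in WT, and *VIM* had 1.47, 1.40, 0.45 and 0.47 without passing. *MRNIP*, at 7932 FPKM, overlaps *SQSTM1*, which encodes the autophagy receptor p62, at 144 FPKM. *MRNIP* rose by 1.19 and 0.96 in WT and 1.28 and 0.96 in KO at 24 h and 48 h, and *SQSTM1* rose by 0.72, 0.70, 0.61 and 0.82.

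*AC092115.2*, at 359 FPKM, overlaps *NQO1*, at 13.5 FPKM. Both were lower in KO at 0 h (-0.82, adjusted p = 0.0463, and -2.05, adjusted p = 0.0371). In KO at 48 h *NQO1* rose by 2.16 (adjusted p = 0.00063) and *AC092115.2* had -0.49 (adjusted p = 0.0586). In KO at 24 h *NT5DC4*, at a mean of 46.8 FPKM, fell by 4.71 (adjusted p = 0.0458). Its partner *CKAP2L*, at 9.13 FPKM, rose by 2.64 (adjusted p = 0.00193). In WT at 48 h *BEST1* and the ferritin gene *FTH1* also parted, at -0.37 (adjusted p = 0.0392) and 0.74 (adjusted p = 0.0105).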
